A study of Rattus norvegicus with 6 samples.

How the data were processed

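Brain RNA of 6 male rats aged 15 weeks, 3 of the SPORTS line and 3 wild type, was labelled with Cy3 and hybridised to 1 single-colour Agilent rat array per rat. Per the labels none of the rats exercised, and no brain region is given. Per the file headers, the intensity values of each array were made with Agilent Feature Extraction 10.10.1.1, which subtracted background and detrended the processed signal within the array without normalising between arrays. The deposited table of all samples holds the same intensity values on a linear scale, multiplied by 1 factor per array between 1.38 and 1.47, and 0 columns of other samples. Its column medians were 376, 376 and 382 for wild type and 394, 384 and 389 for SPORTS. How the authors chose these factors is not given in the sources used here. Spot flags for signal well above background, saturation and outliers were taken from the same files.

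Of 62976 spots, 58717 were not controls, and they carried 30367 distinct probes. Outlier-flagged spot values (3075) were left out and the remaining spots of a probe were averaged on the log2 scale, after which the 75th percentile of each array was subtracted. The 75th percentile of the processed signal was between 1530 and 1628 on the 6 arrays, and the number of arrays limits the precision. A probe was tested if more than 0.5 of its spots were well above background on all arrays of at least 1 group, which kept 20658 probes. Gene symbols came from matching the transcript accession of a probe to a list of RefSeq genes, and 13090 tested probes for 11033 genes had one. No positions are given, because the probe design and the gene list use different genome builds. A gene was represented by its tested probe with the highest mean signal over all 6 arrays, and 1888 genes had more than 1 tested probe.

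SPORTS was compared with wild type with limma 3.58.1 in R 4.3.3 (linear model per probe, moderated test, two-sided, Benjamini-Hochberg adjustment over all tested probes, threshold 0.05); files were read with the data.table package, version 1.17.8. Errors of differences are SE of the fit. For a gene not well above background on any array of 1 group, the fold is a lower bound: the mean of the other group minus the mean, over the dim group's arrays, of the gene's signal or of the lowest normalised signal of any probe well above background, whichever is higher. Lists with 948 gene entries in 43 groups were fixed before the data were examined, and 771 of these entries were tested. A gene in more than 1 list counts once per list. Lists with at least 5 tested members (42) were compared with all other genes with camera of limma at a preset correlation of 0.01, adjusted over the 42 lists. Of the 7 lists that passed, 0 passed with a correlation estimated per list (smallest adjusted p = 0.65, 2 with an unadjusted p under 0.05). The fry test, which asks whether the genes of a list move on balance one way, called 17 lists. Of the lists that passed camera, only the interferon list was not called by fry (fry adjusted p = 0.0815). Among the lists called by fry but not by camera were the catecholamine, serotonin and GABA lists (fry adjusted p = 0.0136, 0.00732 and 0.00214).

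Genes were named by a rule written before the data were examined. It took the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, leaving out LOC and RGD symbols. It added up to 4 called members of each list with the largest differences, up to 2 members with the smallest p of study and cell type lists without a call, the noradrenaline genes Maoa, Slc6a2, Th, Dbh and Adra2a, and at most 3 probes without a symbol. The values of 3 of the genes so named are not reported here. Chosen after their values were seen were Adcy5, B2m, Crh, Drd2, Drd5, Hba-a1, Hbb, Hbb-bs, Lhx6, the cerebellar genes that stood apart in 1 array, Pde10a, Pdyn, Penk, Ppp1r1b, Pts, Rasgrp2, Stat2 and Syndig1l.

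The procedure was tested on simulated data with 200 changed probes among 20657. It recovered 51.5%, 86.1% and 94.3% of those changed 1.5-fold, 2-fold and 4-fold, with 4 false calls among 157. Noise was drawn independently for each probe, without an effect of slide row or an array apart from the rest. The share of changed probes was also lower than the share called in the data, 21.1%, so these rates may not hold for the data. Alternatives were quantile normalisation, a median shift, normexp background correction with an offset of 50, the deposited table, no filter on dim probes, a filter for signal above background on all 6 arrays, keeping outlier spots, a trended and robust variance model, a 2-fold threshold, the mean of a gene's probes, other list tests and leaving out each array. For normexp, planned on the mean spot brightness, the median brightness was used with the local background median. The row of the slide as a block, and slide row 2 alone, were added after seeing the data. Neighbouring genes were taken from the order of genes in the RefSeq list.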

Results

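Brain RNA was profiled from 6 male rats of Wistar background, each 15 weeks old and kept without exercise. Of these, 3 belonged to the SPORTS line, a hyperactive mutant line known for high voluntary running, and 3 were wild type. Each rat contributed 1 single-colour oligonucleotide array. Between 20323 and 23261 of 30367 distinct probes were well above background on an array, and no spot was saturated. Signals are given as normalised log2 values, where 0 is the 75th percentile of the array, and differences are SPORTS minus wild type. The number of arrays limits the precision of every value. Across probes, the correlation was 0.995 to 0.997 between arrays of 1 group and 0.987 to 0.991 between groups. The first principal component held 61.7% of the variance and separated the 2 groups, with scores of -29.9 to -22.0 in wild type and 23.6 to 28.2 in SPORTS.

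The comparison of the 2 lines asks which transcripts differ in the brain of resting SPORTS rats. Transcripts of the striatum were lower in SPORTS, led by the adenosine receptor gene Adora2a, the G protein regulator Rgs9 and the dopamine receptor genes Drd1 and Drd2. The vasopressin gene Avp was 17.9-fold lower. Genes of antigen presentation, interferon-induced genes and genes of fibroblasts and meninges were higher in SPORTS by a median of 1.32-fold, 1.37-fold and 1.49-fold. None of these lists passed with an estimated correlation between genes (adjusted p = 0.65 for the striatal, antigen presentation and meningeal lists, adjusted p = 0.716 for the interferon list). Of the interferon-induced genes, 12 of 23 did not pass, and within slide row 2 their median was 0.24 against 0.45 over all arrays. Several single genes differed much more, among them Serpina5, which was well above background only in SPORTS, and Vegfb, which was so only in wild type. In limma's moderated test, 1424 genes were higher and 1257 lower in SPORTS among 11033 tested, and their median absolute difference was 0.33. At least 2-fold differences were found for 110 genes that were higher and 96 that were lower. At the level of probes, 2283 were higher and 2081 lower among 20658 tested, and 1301 of these called probes had no gene symbol. With the row of the slide as a block, which was chosen after seeing the data, the fit called 445 genes higher in SPORTS and 475 genes lower in SPORTS, and 832 of these were also called without the block. Wild type replicates 1 and 2 lay in slide row 1 and the other 4 arrays in row 2, so differences within row 2 rest on 1 wild type array and equal those of the blocked fit.

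Of the genes with the largest fitted rise, Serpina5, a serine protease inhibitor gene, was not well above background on any wild type array and was at least 21.5-fold higher in SPORTS (limma adjusted p = 0.000143). The same holds for the alpha-globin gene Hba-a3, at least 16.4-fold, and the Notch effector gene Hes1, at least 8.45-fold. C9h6orf141, at least 8.38-fold higher, and Vpreb1b, a surrogate light chain gene of B cell precursors, at least 8.16-fold higher, were also not well above background on any wild type array. Such bounds compare the bright group with the lowest signal that was well above background on each array of the dim group, or with the gene's own signal where that was higher. They hold on the scale of the processed signal. Normexp background correction, whose added offset shrinks differences of dim genes, gave Serpina5 a rise of 2.65 and Hes1 one of 1.56 on the log2 scale. The zinc transporter gene Slc39a12 was measured on all 6 arrays and rose by 3.25 ± 0.14 (SE), from -3.14 ± 0.27 (SD, n = 3) to 0.11 ± 0.04 (n = 3), 9.51-fold (adjusted p = 0.000143). Foxp3, a transcription factor gene of regulatory T cells, rose 11.7-fold and was also above background on all arrays. Rhbdl2, Cnmd and Adtrp, above background on 2 of the 3 wild type arrays, and the olfactory receptor gene Or13p4, above background on 1, also rose, by sizes that depended on the treatment of dim signal. Over the alternatives the rise ran from 2.18 to 3.67 for Rhbdl2, from 1.91 to 3.55 for Cnmd, from 1.67 to 3.25 for Adtrp and from 1.97 to 4.56 for Or13p4, each lowest with normexp.

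Of the genes with the largest fitted fall, Vegfb, a gene of the vascular endothelial growth factor family, had a signal of 0.30 ± 0.06 (SD, n = 3) in wild type and -8.09 ± 0.16 (n = 3) in SPORTS, where no array was well above background. It was at least 93.8-fold lower in SPORTS on the scale of the processed signal (adjusted p = 2.15e-06). With normexp Vegfb fell by 4.72 on the log2 scale, which is less than this bound. Klkb1, which encodes plasma prekallikrein, was at least 5.21-fold lower, the nuclease gene Dnase1 at least 3.54-fold and the cytochrome P450 gene Cyp2c11 at least 6.04-fold. The villin-like gene Vill and the olfactory receptor gene Or10j3b were at least 2.20-fold and 1.98-fold lower, and none of these 5 genes was well above background on a SPORTS array. These bounds also hold on the scale of the processed signal only. Over the alternatives the log2 difference ran from -4.32 to -1.25 for Klkb1, from -3.55 to -0.93 for Dnase1 and from -3.26 to -1.11 for Cyp2c11. It ran from -3.30 to -0.67 for Vill and from -3.36 to -0.66 for Or10j3b, and the smallest difference of each gene was below its bound. Avp, the gene of the hypothalamic hormone vasopressin, fell by 4.17 ± 0.36 (SE) on the log2 scale (adjusted p = 0.00151). The transporter gene Slc35d3 fell by 2.80 ± 0.15, a 6.97-fold difference, and its other probe was also called lower. The homeobox genes Lhx8 and Isl1 also fell, each with 1 of 3 SPORTS arrays above background, so that the sizes are uncertain. Over the alternatives the difference ran from -5.46 to -2.55 for Lhx8 and from -3.35 to -1.003 for Isl1. Calls of 22 of the 24 genes with the largest differences were kept in every alternative, the 2-fold threshold and the mean of a gene's probes apart. Lhx8 lost its call with the slide row as a block (adjusted p = 0.0613) and within row 2, and its adjusted p ran from 8.48e-05 to 0.103 over the alternatives. Isl1 lost its call with the block, without the filter on dim probes and without any 1 of wild type replicates 1 to 3 or SPORTS replicate 2 (adjusted p up to 0.0680), and its adjusted p ran from 0.000511 to 0.191 over the alternatives. Except for Slc35d3, each of the 24 genes was tested with 1 probe. Of the probes without a gene symbol, A_64_P081939, A_64_P140148 and A_64_P010923 were not above background on any wild type array and were at least 8.40-fold, 4.38-fold and 6.93-fold higher in SPORTS.

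**Figure D1:**
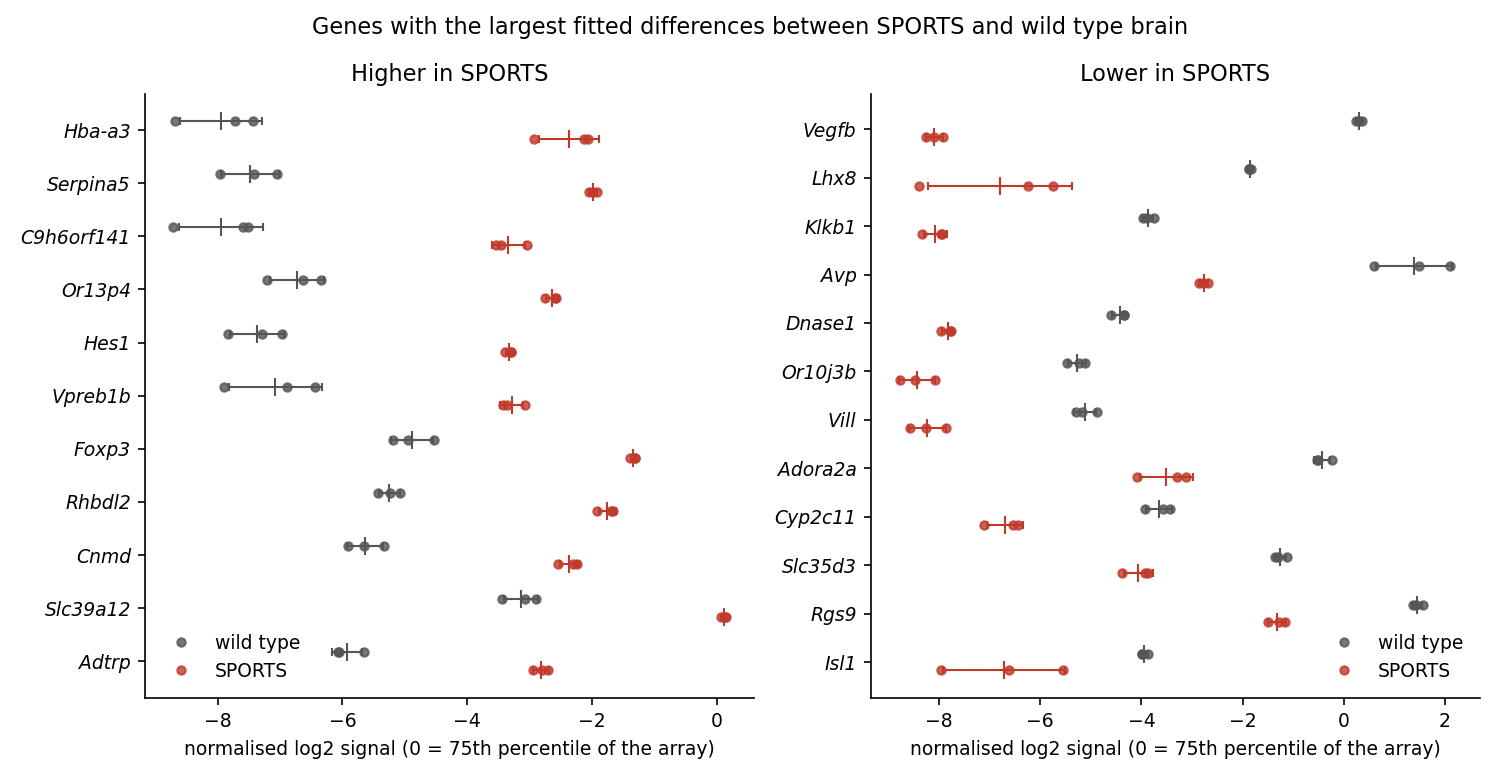
Normalised log2 signal (0 is the 75th percentile of the array) of 11 of the 12 genes with the largest fitted rise and of the 12 with the largest fitted fall in SPORTS. Points are single arrays (3 wild type in grey, 3 SPORTS in red), ticks are group means and bars are SD; the rule took genes whose groups do not overlap, and Vegfb lies near 0.30 in wild type and near -8.09 in SPORTS.

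The list of dopamine receptors and striatal projection neuron genes had the lowest median of the 43 lists fixed in advance. Of its 14 tested members, 13 fell and none rose, and the median difference was -1.53, a 2.88-fold fall (camera adjusted p = 8.69e-11). Adjusted over the list alone, 13 were lower and 1 higher. With an estimated correlation between genes, adjusted p = 0.65. Adora2a, whose receptor is abundant on striatal neurons that project to the external pallidum, fell by 3.08 ± 0.26 (SE). Rgs9, a regulator of G protein signalling enriched in striatum, fell by 2.77 ± 0.10 (adjusted p = 0.000108). The D1 receptor gene Drd1, above background on 1 of 3 SPORTS arrays, fell by an uncertain size, with differences from -2.79 to -1.15 over the alternatives. Other members that fell were Penk, Drd2, Ppp1r1b, Tac1, Syndig1l, Pdyn, Rasgrp2, Pde10a and Adcy5, which fell by between 1.94 (Penk) and 0.72 (Adcy5). Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, fell 3.56-fold, and the second probes of Drd2, Ppp1r1b and Tac1 also fell. The D5 receptor gene Drd5 had a difference of 0.27 ± 0.08 (adjusted p = 0.0639). Within slide row 2 the median was -1.46, and 13 members were lower and 1 higher with the row as a block. Over all 6 arrays the pan-neuronal markers had a median of -0.03 and the astrocyte markers one of 0.15, and within slide row 2 these medians were -0.07 and 0.11.

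**Figure D2:**
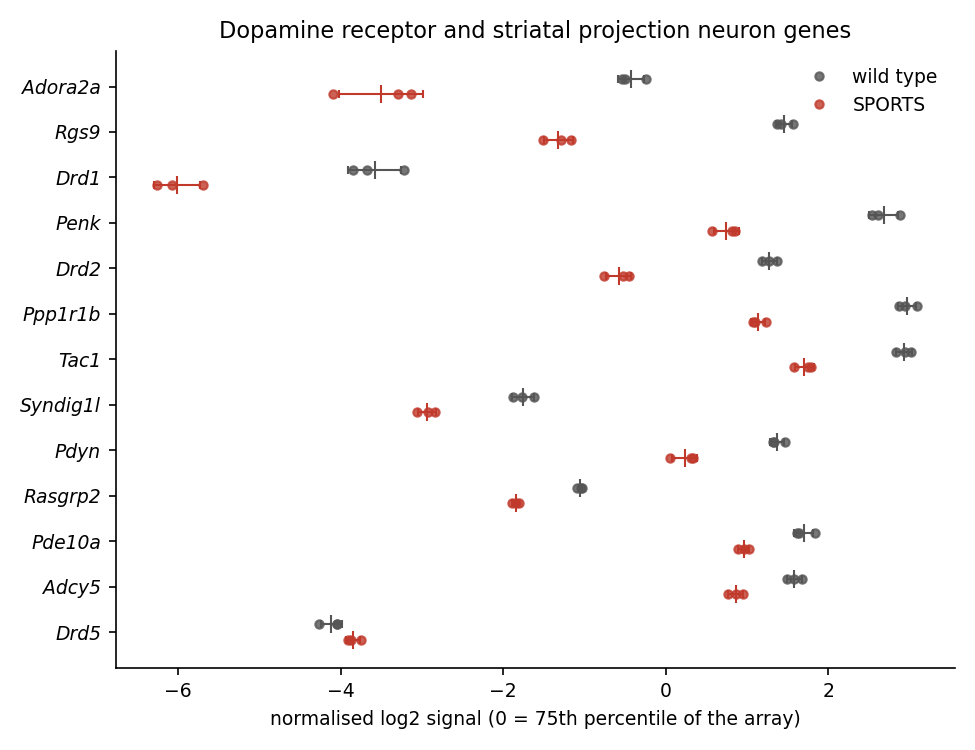
Normalised log2 signal (0 is the 75th percentile of the array) of 13 of the 14 tested members of the list of dopamine receptors and striatal projection neurons. Points are single arrays (3 wild type in grey, 3 SPORTS in red), ticks are group means and bars are SD; every SPORTS array lies below every wild type array for all genes shown but Drd5, which differs by 0.27 in the other direction.

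Catecholamine genes were of interest because altered noradrenaline handling has been described in the SPORTS line. Of 17 tested genes of catecholamine synthesis, transport and breakdown, 4 rose and 1 fell, and the list did not pass (median 0.56, camera adjusted p = 0.0646). Adjusted over the list alone, 8 were higher and 2 lower. Gchfr, a regulator of tetrahydrobiopterin synthesis, rose by 0.62 ± 0.06 (SE). Pts, also of tetrahydrobiopterin synthesis, rose by 0.22 ± 0.03, and its call ended with the slide row as a block (adjusted p = 0.0673; range over the alternatives 0.00739 to 0.0903), while the vesicular transporter gene Slc18a1 fell by 1.22 ± 0.08 (from -1.27 to -0.70 over the alternatives). Ddc, which encodes the decarboxylase that makes dopamine and serotonin, rose by 1.05 ± 0.25 (adjusted p = 0.0345). Its call ended with the slide row as a block (adjusted p = 0.256) and without wild type replicate 2 or any 1 of the SPORTS arrays (adjusted p up to 0.106), and the adjusted p ran from 0.0137 to 0.256 over the alternatives. Monoamine oxidase A, encoded by Maoa, differed by 0.15 ± 0.05 and did not pass (adjusted p = 0.0925), except with normexp (adjusted p = 0.0316; range over the alternatives 0.0316 to 0.217). Th, the rate-limiting enzyme of catecholamine synthesis, did not pass either, at 0.56 ± 0.28 (adjusted p = 0.217). The difference of Th was 0.25 without wild type replicate 1 and 0.24 with the slide row as a block. Adra2a, an inhibitory adrenergic receptor gene, did not pass at -0.02 ± 0.08 (adjusted p = 0.875), and its sign differed between alternatives. The noradrenaline transporter gene Slc6a2 differed by 1.13 ± 0.59 (adjusted p = 0.235), with SPORTS replicate 1 at -1.77 and the other 5 arrays between -4.47 and -3.49. Dbh, which encodes the enzyme that makes noradrenaline, differed by 0.73 ± 1.25 (adjusted p = 0.730). Its signal was -1.55 in SPORTS replicate 1, -6.25 and -5.87 in SPORTS replicates 2 and 3 and -5.28 ± 0.21 (SD, n = 3) in wild type. The same array stood apart on markers of the cerebellum, chosen after their values were seen: Pcp2 was at -0.51 in SPORTS replicate 1 and between -3.75 and -3.54 in the other 5 arrays, and Car8 was at 0.34 against -1.59 to -1.43. Without SPORTS replicate 1 the difference of Dbh was -0.78 (adjusted p = 0.0486) and that of Slc6a2 0.45 (adjusted p = 0.241).

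**Figure D3:**
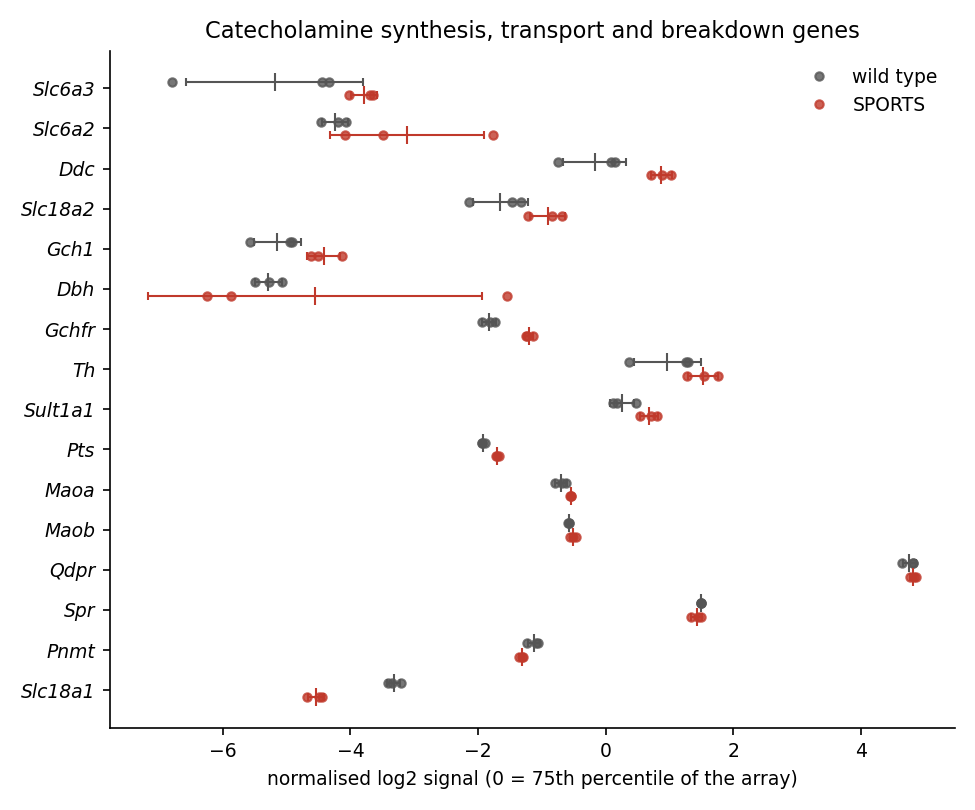
Normalised log2 signal (0 is the 75th percentile of the array) of 16 of the 17 tested genes of catecholamine synthesis, transport and breakdown. Points are single arrays (3 wild type in grey, 3 SPORTS in red), ticks are group means and bars are SD; Slc6a2 and Dbh spread widely in SPORTS because of 1 array, at -1.77 and -1.55.

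Receptor genes of other transmitters moved in both directions. Of 9 tested serotonin system genes, 2 rose and 4 fell, and the list did not pass (camera adjusted p = 0.273; the test and the median point down and the mean up). Tph2, the rate-limiting enzyme gene of brain serotonin synthesis, rose by 1.48 ± 0.23 (SE), but its call ended with the slide row as a block (adjusted p = 0.0592; range over the alternatives 0.00218 to 0.0990), and its difference ran from 0.87 to 1.72. The receptor genes Htr1d and Htr2a fell by 1.62 ± 0.16 and 0.84 ± 0.06, with Htr1d above background on 2 of 3 SPORTS arrays (difference from -1.78 to -0.75 over the alternatives). Of 15 acetylcholine system genes, 1 rose and 5 fell (adjusted p = 0.239), among them the muscarinic receptor gene Chrm1, with a difference from -1.56 to -0.72 over the alternatives. Chrm4, another muscarinic receptor gene, fell by 0.60 ± 0.05. Of 13 genes of adrenergic receptors and their regulators, 1 rose and 3 fell (adjusted p = 0.245). Adra2b fell by 0.33 ± 0.05. The call of Adra1d, the gene that rose, ended with the slide row as a block (adjusted p = 0.115; range over the alternatives 0.00146 to 0.137). Adra2c lost its call with the block and without SPORTS replicate 3 or any 1 wild type array (adjusted p from 0.00752 to 0.172 over the alternatives), and Adrb3 with the block and without any 1 array but wild type replicate 3 (0.0269 to 0.260). Of 29 glutamate receptor and transporter genes, 4 rose and 8 fell (adjusted p = 0.0845). The metabotropic receptor genes Grm5 and Grm8 moved apart, by 1.21 ± 0.10 and -0.91 ± 0.06, and the AMPA receptor subunit gene Gria1 fell by 0.61 ± 0.04. Of 26 GABA system and interneuron genes, 1 rose and 4 fell (adjusted p = 0.143), and the neuropeptide genes Sst and Npy fell by 1.13 ± 0.06 and 0.80 ± 0.07.

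Among 20 genes of feeding, arousal and other hypothalamic peptides, none rose and 5 fell, and the list did not pass (median -0.25, and -0.71 within slide row 2; camera adjusted p = 0.0646). The 5 were Avp, Sst, Npy, the gonadotropin-releasing hormone gene Gnrh1, which fell by 0.85 ± 0.10 (SE; from -0.93 to -0.43 over the alternatives), and the corticotropin-releasing hormone gene Crh, which fell by 0.34 ± 0.08. The call of Crh ended with the slide row as a block (adjusted p = 0.180), without the filter on dim probes and without any 1 array but SPORTS replicate 1, and its adjusted p ran from 0.0114 to 0.187 over the alternatives. The hypothalamus regional markers passed with 5 of 6 tested members lower and a median of -1.13 (camera adjusted p = 0.0105; adjusted p = 0.65 with an estimated correlation). These were the developmental transcription factor genes Lhx8, Isl1, Six3, Nkx2-1 and Lhx6, several of which are also active in the basal forebrain and striatum, and with the slide row as a block 1 member was called. Nkx2-1 also lost its call without any 1 array but SPORTS replicate 3 (adjusted p from 0.0274 to 0.164 over the alternatives). Without the filter on dim probes this list did not pass (median -0.03, adjusted p = 0.0681; range over the alternatives 0.00132 to 0.0681). The olfactory bulb regional markers passed with 4 of 10 members lower and 1 higher (median -0.20, camera adjusted p = 0.0105; adjusted p = 0.65 with an estimated correlation). Cdhr1, a cadherin gene of olfactory bulb projection neurons, fell by 1.53 ± 0.09, and the interneuron homeobox genes Dlx5 and Dlx1 fell by 1.42 ± 0.10 and 0.51 ± 0.07. Within slide row 2 the medians of the 2 lists were -1.19 and -0.17. Adjusted over each list alone, 5 hypothalamic and 6 olfactory bulb markers were lower and 0 and 1 higher. Other regional lists did not pass. Of the cortex and hippocampus markers 1 of 19 rose and 3 fell (camera adjusted p = 0.144). Of the thalamus and epithalamus markers 1 of 13 rose and 1 fell (adjusted p = 0.224). Of the cerebellum markers 0 of 15 rose and 2 fell (adjusted p = 0.714), with 1 array apart from the rest. Of the hindbrain and spinal markers 2 of 9, Slc6a5 and Tph2, rose and 1, Tac1, also of the striatal list, fell (adjusted p = 0.428). The median of the hindbrain and spinal list was 0.56, and 0.24 within slide row 2, with 6 members above 0 and 3 below. SPORTS replicate 1 was the highest of the 6 arrays for the cerebellar genes Pcp2 (-0.51, the others at most -3.54), Car8 (0.34, the others at most -1.43), Cbln1 (0.34, the others at most -0.42), Ppp1r17 (-3.45, the others at most -5.00), Slc1a6, Neurod1 and Cbln3, named after their values were seen. Without this array the striatal list had a median of -1.47 and the fit called 892 genes higher in SPORTS and 876 genes lower in SPORTS.

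Genes of MHC and antigen presentation rose together: 14 of 23 tested members were higher, none was lower, and the median difference was 0.40 (camera adjusted p = 2.12e-06; adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone, 20 were higher. The beta-2-microglobulin gene B2m, which encodes the shared subunit of class I molecules, rose by 0.42 ± 0.05 (SE, adjusted p = 0.00354), and the class I gene RT1-A2 rose by 0.49 ± 0.06. The immunoproteasome subunit gene Psmb8 rose by 0.60 ± 0.09, and its call ended with the slide row as a block (adjusted p = 0.0908; range over the alternatives 0.00138 to 0.134). Values of single RT1 genes are uncertain because these genes share sequence. For the same reason the count of members that rose may not reflect separate changes. Interferon-induced genes passed camera with 10 of 23 members higher and 1, Stat2, lower (median 0.45, camera adjusted p = 0.00181). The list did not pass with an estimated correlation (adjusted p = 0.716) or with the fry test (adjusted p = 0.0815). The counts were the same adjusted over the list alone. Irf7, a transcription factor gene of the interferon response, rose by 1.54 ± 0.40, Isg15 by 1.22 ± 0.32, Oas1a by 1.15 ± 0.29 and Ifi44 by 0.71 ± 0.18. Irf7 was at -2.76 and -2.66 in wild type replicates 1 and 2, at -1.33 in wild type replicate 3 and between -0.85 and -0.48 in SPORTS. The calls of Irf7, Isg15, Oas1a and Ifi44 ended with the slide row as a block, with adjusted p from 0.0986 (Irf7) to 0.296 (Oas1a) and smaller differences of 0.62 for Irf7, 0.52 for Isg15, 0.67 for Oas1a and 0.33 for Ifi44. They also ended when any 1 array other than wild type replicate 3 was left out, and over the alternatives the adjusted p ran from 0.00269 to 0.140 for Irf7 and from 0.0325 to 0.339 for Oas1a. Within slide row 2 the median was 0.33 for the MHC list and 0.24 for the interferon list. Over all 6 arrays the meningeal and fibroblast markers had a median of 0.58, the leukocyte markers 0.20 and the microglia and macrophage markers -0.01, and within slide row 2 these medians were 0.71, 0.27 and 0.04. With the row as a block 3 MHC members were called higher and 0 interferon members were called in either direction. The call of Stat2 also ended without the filter on dim probes and without any 1 of wild type replicates 2 and 3 or SPORTS replicates 2 and 3 (adjusted p from 0.0110 to 0.149 over the alternatives). Of 16 inflammation and acute phase genes 5 rose and 1 fell, and the list did not pass (adjusted p = 0.0646). Il18, a cytokine gene, rose by 0.43 ± 0.05.

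Among the cell types, markers of meninges and fibroblasts rose most: 13 of 18 were higher and 1 lower, with a median of 0.58 (camera adjusted p = 7.45e-06; adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone, 16 were higher and 1 lower. The proteoglycan gene Dcn rose by 1.12 ± 0.05 (SE, adjusted p = 0.000143) and the collagen gene Col1a2 by 0.84 ± 0.10, while Ogn, another small proteoglycan gene, fell by 0.92 ± 0.11. Within slide row 2 the median was 0.71, and 10 were higher and 1 lower with the row as a block. Astrocyte markers also passed, with 5 of 15 higher, none lower and a median of 0.15 (camera adjusted p = 0.0105; adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone, 6 were higher. The connexin gene Gjb6 rose by 0.58 ± 0.06 and the water channel gene Aqp4 by 0.57 ± 0.08, and the call of Aqp4 ended with the slide row as a block (adjusted p = 0.0539; range over the alternatives 0.000736 to 0.0558). The median of this list was 0.11 within slide row 2, where 1 member was called with the block. Of 20 oligodendrocyte and myelin markers 5 rose and none fell, and the list did not pass (adjusted p = 0.0646); Cldn11, a tight junction gene of myelin, rose by 0.39 ± 0.05. Of 19 microglia and macrophage markers none rose and 3 fell (adjusted p = 0.356), among them Tmem119 and Fcrl2, which fell by 0.77 ± 0.06 and 0.85 ± 0.10. Of the pan-neuronal markers 4 of 15 rose and 4 fell (adjusted p = 0.529; the test and the median point down and the mean up), with the neurofilament gene Nefh at 0.93 ± 0.10 and the growth cone gene Gap43 at -0.52 ± 0.04. Of 16 endothelial markers 4 rose, and of 13 pericyte and smooth muscle markers 3 rose and 1 fell (adjusted p = 0.0994 and 0.144). Of 8 leukocyte markers 2 rose (adjusted p = 0.224), among them Camp, an antimicrobial peptide gene of neutrophils, by 0.95 ± 0.09 (0.55 with normexp). Of 8 red blood cell markers 1, Ahsp, rose (adjusted p = 0.871), and the list members Hba-a1 and Hbb differed by 0.03 and 0.08 and changed sign between alternatives. Ahsp, a chaperone gene of alpha-globin, lost its call with the slide row as a block and without any 1 of wild type replicates 1 and 2 or SPORTS replicates 1 and 2 (adjusted p from 0.0102 to 0.229 over the alternatives). Globin genes share sequence, so the rise of Hba-a3 is uncertain. The oligodendrocyte precursor markers (1 of 11 higher, 1 lower, adjusted p = 0.877, with a positive median and a negative mean and test) and the ependymal and ciliated cell markers (1 of 10 higher, 1 lower, adjusted p = 0.689) did not pass. None of 19 choroid plexus markers was called (adjusted p = 0.385), and none of the 4 measured pituitary hormone genes, too few for the list test.

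**Figure D4:**
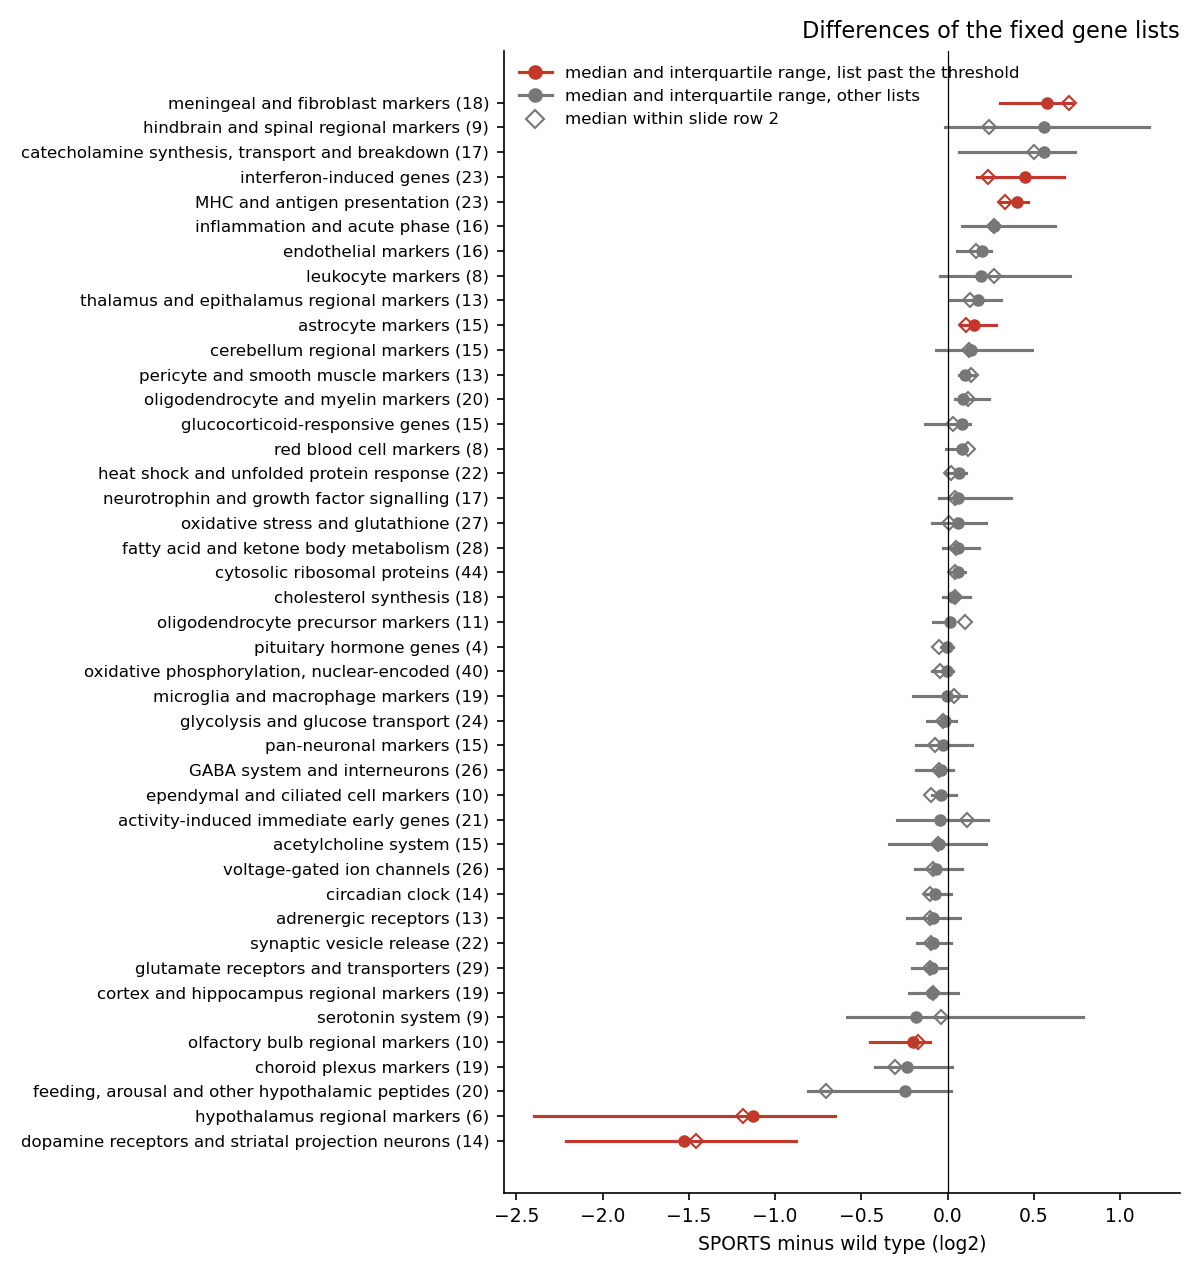
Median difference (SPORTS minus wild type, log2) of the 43 gene lists fixed in advance, with the number of tested genes in parentheses. Circles are medians over the genes of a list, lines run from the lower to the upper quartile of its genes, diamonds are medians within slide row 2, and red marks the 7 lists past the camera threshold, from -1.53 for the striatal list to 0.58 for the meningeal list.

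Lists of growth factors, cell state and metabolism did not pass. Of 17 neurotrophin and growth factor genes 6 rose and 4 fell (camera adjusted p = 0.424), with the binding protein genes Igfbp2 and Igfbp4 moving apart, by 0.61 ± 0.08 (SE) and -0.67 ± 0.06. Of 21 activity-induced immediate early genes none rose and 2, Egr2 and Homer1, fell (adjusted p = 0.762). Egr2 lost its call with the slide row as a block and without any 1 array but SPORTS replicate 2 (adjusted p from 0.0184 to 0.279 over the alternatives), and Homer1 fell by 0.31. Of 26 voltage-gated ion channel genes 1 rose and 7 fell (adjusted p = 0.181), led by the sodium channel beta subunit gene Scn4b, which fell by 1.12 ± 0.05. Of 22 synaptic vesicle release genes 2 rose and 4 fell (adjusted p = 0.112), and Stx1a, a syntaxin gene, fell by 0.53 ± 0.04. Of 44 cytosolic ribosomal protein genes 2 rose and 2 fell (adjusted p = 0.0845), and Rpl13 fell by 1.15 ± 0.05. Of 40 nuclear-encoded oxidative phosphorylation genes 1 rose and 4 fell (adjusted p = 0.239), and of 24 genes of glycolysis and glucose transport 1 rose and 3 fell (adjusted p = 0.385). Of 28 genes of fatty acid and ketone body metabolism 5 rose and 3 fell (adjusted p = 0.323), among them the fatty acid transporter gene Cd36, above background on 2 of 3 SPORTS arrays, at -0.78 ± 0.11 (from -0.90 to -0.25 over the alternatives). Of 18 cholesterol synthesis genes 3 rose (adjusted p = 0.277). Of 27 oxidative stress and glutathione genes 6 rose and 4 fell (adjusted p = 0.322), with the glutathione transferase gene Gsta4 at 0.56 ± 0.05. Of 22 heat shock and unfolded protein response genes 3 rose and 2 fell (adjusted p = 0.323), of 15 glucocorticoid-responsive genes 3 rose and 2 fell (adjusted p = 0.689), and of 14 circadian clock genes 1 fell (adjusted p = 0.239).

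For the other fixed lists, the counts adjusted over the list alone were as follows where they differed from those over all probes. Of the transmission lists, the adrenergic list had 1 gene higher and 4 lower, the serotonin list 3 and 4, the glutamate list 4 and 9 and the vesicle release list 3 and 9. The hypothalamic peptide list had 0 higher and 6 lower, the immediate early list 0 and 1 and the neurotrophin list 7 and 4. The inflammation list had 8 higher and 1 lower, the pan-neuronal list 4 and 6, the endothelial list 7 and 1 and the cortex and hippocampus list 1 and 5. The oxidative phosphorylation list had 0 higher and 2 lower, and the ribosomal list 1 and 2.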

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

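The tests with the slide row as a block and within slide row 2 were chosen only after the data were seen. For the mean of a gene's probes and the other list tests only counts were kept, so directions, calls and ranges of single genes and lists cover the remaining alternatives. In these, no list that passed and no named called gene reversed its direction. For Rps16, a named called gene, the representative probe fell by 0.29 and the other tested probe rose by 1.91. Of the genes not called, Adra2a ran from -0.10 to 0.07, and Dbh was called at -0.78 only without SPORTS replicate 1. Maoa was called only with normexp. Drd5 ran from 0.18 to 0.42 and was called only with normexp and with the slide row as a block. The lists for striatum, MHC, interferon, meninges, astrocytes and olfactory bulb passed camera in every alternative with a preset correlation for which single lists were kept. There the camera adjusted p ran from 2.19e-12 to 2.49e-08 for the striatal list and from 8.19e-06 to 0.0476 for the interferon list. The hypothalamus list had a median of -0.0278 without the filter on dim probes and did not pass there; with the filter for all 6 arrays it had too few members to test. The number of lists past the threshold, 7, was 11 with quantile normalisation, 14 with the mean of a gene's probes, 12 within slide row 2, 0 with an estimated correlation and 17 with fry; the cause was not tested.

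Without the filter on dim probes, there were 1234 probes higher in SPORTS and 1108 probes lower in SPORTS, and 767 genes higher in SPORTS and 676 genes lower in SPORTS, with more probes in the adjustment. At least 2-fold differences, a stricter threshold by construction, left 198 probes higher and 151 lower (110 and 96 genes). With the slide row as a block, 741 probes were higher and 856 lower (445 and 475 genes), and within slide row 2, 598 were higher and 622 lower (352 and 337 genes). Both compare SPORTS with 1 wild type array, which is assumed to vary like the others. Leaving out 1 array, so that 1 group has 2, gave 1356 (without SPORTS replicate 3) to 1786 probes higher and 1123 (without SPORTS replicate 2) to 1558 lower, 839 to 1075 genes higher and 678 to 928 lower, and 7 to 12 lists (12 without wild type replicate 1). Of called genes, 53.1% were higher, 43.1% with the median shift and 56.8% with the deposited table. Of 157 named called genes, 8 lost their call with quantile normalisation, 6 with the median shift, 1 with normexp, 0 with the deposited table, 2 with outlier spots kept, 4 with the other variance model, 52 without the filter, 80 with the row as a block, 88 within row 2 and 33 to 45 without 1 array. With normexp, 40 of the 157 differences were smaller by over 1.5 times, and 9 with the row as a block. Signal over background limits the folds of genes dark in 1 group.

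Slide and scan date as blocks were not run, because all 6 arrays share 1 slide and 1 scan time. No paired analysis was possible because replicate numbers do not link rats of the 2 groups.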

Other observations

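The tests of the neuron share, slide position, microglia, leukocytes and other splits of the arrays were chosen only after the results they concern were seen. The 2 gene sets of the next sentences were written after the striatal list had been seen and before their own values were. Of 17 tested further genes enriched in striatum, 16 fell, with a median of -0.77 (camera p = 2.46e-12 from limma, p = 0.018 with an estimated correlation). Among them, Gng7, which encodes a G protein subunit that couples striatal receptors to adenylyl cyclase, fell by 1.26 ± 0.09 (SE), the retinoid receptor gene Rxrg by 1.13 ± 0.07 and the phosphodiesterase gene Pde1b by 0.97 ± 0.07. Of 6 tested markers of forebrain cholinergic neurons, 4 fell, with a median of -0.53 (camera p = 0.00212, p = 0.0345 with an estimated correlation), and 4 of the 6 are also in other lists. The neurotrophin receptor gene Ngfr fell (adjusted p = 0.00511), and Chat, the gene of the acetylcholine-making enzyme, differed by -0.15 ± 0.23 (adjusted p = 0.690). The beta-globin gene Hbb-bs, chosen after its value was seen, rose by 2.14 ± 0.26 (adjusted p = 0.00412), while Hbb differed by 0.08.

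For the striatal genes that were lower in SPORTS, a lower share of neurons in general is argued against by the pan-neuronal markers. Their median was -0.0265 against -1.53 for the striatal list. These markers cannot show a loss limited to striatal neurons, because other neurons carry them too. The row of the slide as the cause of most of the difference is argued against by the median within slide row 2, -1.46. The SD of the list median between arrays of a group, pooled over all 6 arrays, was 0.087. Row 2 held 1 wild type array, in column 1, and the SPORTS arrays in columns 2 to 4. Position along the row therefore could not be told apart from the line and stays open. Less striatal or neighbouring ventral forebrain tissue in the SPORTS samples may account for the pattern: the further striatal genes had a median of -0.772 and the cholinergic markers one of -0.533. Lower expression in the striatum of the SPORTS line stays open as well and was not tested, because no brain region is given for the samples.

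For the single genes with very large differences, such as Serpina5 and Vegfb, a sequence variant under a single probe could give a signal in 1 line only. Among 43 genes with a called probe that differed at least 2-fold and with other tested probes, 56.9% of 51 other probes were called the same way (95% Clopper-Pearson interval 42.2% to 70.7%). The interval treats probes of 1 gene as independent, and the 43 genes included striatal genes such as Drd2 and Ppp1r1b. The share lay between the 25% and 75% set in advance, so a sequence variant under a single probe stays open. It also stays open because 182 of 206 genes with at least 2-fold differences had 1 tested probe. Inherited chromosome blocks that differ between the lines may bring neighbouring genes along: 4 neighbouring pairs were found against a median of 3 in 10000 shuffles of the gene order (permutation p = 0.5, one-sided), which leaves this open too. A change in the regulation of these genes in the SPORTS line was not tested.

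For the MHC genes that were higher in SPORTS, more microglia is argued against by the microglia and macrophage markers, whose median was -0.00650 (quartiles -0.20 and 0.10; 0.04 within slide row 2) against 0.40 for the MHC list. The slide row as the cause of most of the MHC difference is argued against by the median of 0.332 within slide row 2. The SD between arrays of a group, pooled over all 6 arrays, was 0.070. Position along the row stays open, because row 2 held 1 wild type array, in column 1. For the interferon-induced genes the median within slide row 2 was 0.236 against 0.45 over all arrays, with an SD of 0.207. For them array position as a whole stays open. More leukocytes could also raise the MHC genes. The 8 leukocyte markers, 0 of them in another list, had a median of 0.196 (quartiles -0.04 and 0.71). Camp was at 0.95 and the pan-leukocyte gene Ptprc at 0.31 (from 0.18 to 0.52 over the alternatives). The call of Ptprc ended without wild type replicate 1 or any 1 SPORTS array (limma adjusted p from 0.0125 to 0.0822 over the alternatives). The share of leukocytes therefore stays open. The meningeal and fibroblast markers had a median of 0.58, above that of the MHC list, and 0.71 within slide row 2. Their share in the samples was not tested as a cause of the MHC difference and stays open as well. A difference in immune activity between the lines was not tested.

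The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4364 probes and the highest of the other splits called 0, so 1 of the 10 splits reached the real count.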
